A study of Mus musculus with 12 samples.

How the data were processed

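The samples were 12 preparations of total RNA from mouse CD4+ T cells, each hybridised to 1 array of an Illumina mouse BeadChip. In the first experiment naive CD4+ T cells had been exposed to interleukin-7 (IL-7) for 0, 6 or 24 h, with 2 arrays per time. In the second, Th9 cells had been grown either from untreated naive cells or from naive cells first given IL-7, with 3 arrays per group. Groups and replicate numbers were taken from the labels. The sources used here do not say whether replicates were separate animals, separate cultures or the same culture hybridised again. Each experiment sat on its own BeadChip, per the labels.

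The deposited intensity of each of the 45281 probes is a background-subtracted signal on a linear scale, which can be negative and was not normalised between arrays. It comes from GenomeStudio, per the submitters' processing notes, which name no version. The detection p-value of each probe on each array was deposited beside it. A second deposited table of intensity values, also linear, had been scaled array by array. Its column means ran from 204.7 to 207.1 in the first experiment and from 171.6 to 173.3 in the second. In the order 0, 6 and 24 h, its column medians were 4.3, 4.8 and 5.2 for replicate 1 and 4.2, 4.6 and 4.4 for replicate 2. They were 3.4, 2.9 and 2.7 for the Th9 arrays without IL-7 and 3.1, 3.4 and 3.2 for those after IL-7. Scale and direction of these values are known, while the step that set their level (which probes entered the average) stays unknown.

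The probe names of the scaled table could not be used. Values were given on 30854 of its lines and missing on 14427. Of 1244 bright lines, 853 (68.6%) had the same profile over the 12 arrays as a probe of the unscaled table, within a log2 distance of 0.005 after 1 factor per array, and 0 of these carried the same probe name. Spearman correlations between the tables for probes of the same name lay between -0.008 and 0.002. The 43 probes for T cell identity and glycolysis genes had a median percentile of 89.2 in the unscaled table and 27.9 in the scaled one. The same matching was run on a copy of the unscaled table multiplied by 1 random factor per array (1387 bright lines). It placed 100% of the lines, with 100% under their own name when names were kept and 0% when they were shuffled. This checks the code and not the share matched in the scaled table. All values therefore come from the unscaled table, and from the scaled table only its factor per array (0.74 to 1.41) was used, as an alternative scaling.

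Gene symbols came from a table that pairs probe names with symbols: 34885 probes carried 1 symbol, 18 several and 10378 none. Symbols were matched to a mouse RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 0 of them. No genome build was used for the probes, and no positions are given.

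Signals were background-corrected, quantile-normalised and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3 (normexp model, negative control distribution inferred from the detection p-values, offset 16), separately for the 6 arrays of each experiment. Features were kept when the detection p was under 0.01 on at least 2 arrays of the first experiment or 3 of the second. Each gene symbol was represented by the probe with the highest mean, and probes with no symbol were kept as features of their own. Linear models and moderated tests (lmFit, eBayes) were fitted with limma to the 3 groups of the first experiment (3 residual degrees of freedom) and the 2 groups of the second (4 residual degrees of freedom). The p-values are 2-sided and adjusted by Benjamini and Hochberg over the features tested, and a feature was called at an adjusted p under 0.05. The difference between the IL-7 effects in the experiments was tested as a contrast over all 12 arrays normalised together, on features detected on at least 2 of them. Errors of log2 fold changes are standard errors from the fit, and errors of group means are standard deviations. Where a probe was not detected on any array of a group, the fold is given as a bound, with the undetected side raised to the lowest detected value of each array. The number of arrays limits the precision.

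A total of 35 gene lists (pathways, helper T cell subsets and markers of other cell types) and the comparisons, filters and tests were fixed before the data were examined. Where no probe carried a listed symbol, a gene with that symbol among its synonyms could stand in for it. Amd2 thus stood in for Amd1 among the polyamine and nucleotide synthesis genes, and Eno1b for Eno1 and Pigq for Gpi1 among the glycolysis genes. Some lists share genes, so their results are not independent. Il2ra, Ctla4, Tnfrsf4, Tnfrsf18 and Tnfrsf9 are in both the regulatory T cell and the T cell activation lists. Il2ra and Tnfrsf4 are also among the STAT5 targets, and Fcer1g and Tyrobp are in both the myeloid and the natural killer cell lists. Lists with at least 5 measured members were tested against all other genes with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. In the second form camera also takes its p-values from the residual degrees of freedom of the fit (3 or 4). Its p-values are therefore larger even where the genes of a list do not correlate. The rule for naming genes was fixed at the same time. It takes, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall, if their replicates do not overlap between the groups, the gene is detected on every array of the higher group and the symbol is not a clone or predicted name. It adds up to 3 called members of each list, by size of change, and 15 genes whatever their result: Il9, Foxo1, Foxp1, Foxp3, Il7r, Bcl2, Cish, Socs2, Irf4, Spi1, Gata3, Il21, Klf2, Ep300 and 1 that is not reported here. Other genes are said to have been chosen after their values were seen.

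The calls at 6 h and 24 h share the arrays at 0 h, so their overlap was set beside that in 100 simulated sets of unchanged arrays. The same code was tested on simulated arrays with known changes. The changed genes were drawn from those outside the lists and detected on all 6 arrays of an experiment, with noise independent between genes. The shares below therefore do not cover dimmer genes or an array that deviates across many genes. Genes changed 1.5-fold, 2-fold and 4-fold were called in 12.1%, 79.7% and 100% of cases in the design of 6 h against 0 h (11100 features), and 7.7% of its calls were unchanged genes. The corresponding shares were 6.2%, 80% and 95.3%, with 5.1% unchanged, for 24 h against 0 h (11116 features). For 24 h against 6 h (11110 features) they were 13.6%, 85.9% and 96.8%, with 8.6% unchanged. In the Th9 design (10100 features) they were 21.5%, 78.5% and 100%, with 5% unchanged, and for the difference of effects (12246 features) 7.9%, 41% and 90.8%, with 3.2% unchanged. No call had the wrong sign.

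Alternatives fixed in advance changed the background and scaling, the detection filter, the choice of probe, the variance model, array weights, the arrays in the fit and a replicate block, or left out each array in turn. Scaling by the factors of the second table was chosen after seeing the data. Further analysis and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.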

Results

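Gene expression was measured in CD4+ T cells from the spleens of mice 2 months old, on 12 arrays with 45281 probes each. The sample labels name a strain with a transgenic T cell receptor on the C57BL/6 background and the design text names C57BL/6 mice, so the strain of each experiment is not certain. In the first experiment naive CD4+ T cells, which have not yet become a helper subset, were exposed to IL-7, a cytokine that naive T cells need for survival, for 0, 6 or 24 h, with 2 arrays per time. In the second, naive CD4+ T cells were grown for 3 days into Th9 cells, the helper T cells named after interleukin-9. They were grown either without IL-7 or after 48 h of IL-7, with 3 arrays per group. Mean signal per array ran from 157.6 to 245.2 in the first experiment and from 116.1 to 221.6 in the second, and 32.1% to 34.5% and 28.3% to 32.1% of the probes were detected. The only cells without IL-7 in the first experiment are those at 0 h, so each change there covers IL-7 and time in culture together. Whether the replicates are separate animals or cultures is not given in the sources used here, and p-values measure only the spread between these samples, which may be technical. Replicate arrays correlated at 0.993 at 0 h and 0.992 at 24 h, and at 0.962 at 6 h.

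The array of 6 h replicate 1 carried transcripts of other cell types. The genes named here belong to lists of cell type markers and sex-linked transcripts fixed beforehand, but were picked from them after their values were seen. Cd74 and H2-Ab1, genes of antigen-presenting cells, had deposited signals of 4418.3 and 2675.4 there, against at most 230.4 and 127.3 on the other 5 arrays of the experiment. The macrophage genes Lyz2 and C1qb had 884.2 and 439.1, against at most 70.6 and 17.2. All 8 measured B cell markers and 13 of 14 measured myeloid and dendritic cell markers were highest on this array after normalisation, and 8 and 10 by deposited signal. Xist, transcribed from the inactive X chromosome of female cells, had a signal of 692 on this array and was not detected on the other 5. The Y-linked Eif2s3y was lower there, at 358, than on the other 5 arrays, at 819 to 1238.

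**Figure D1:**
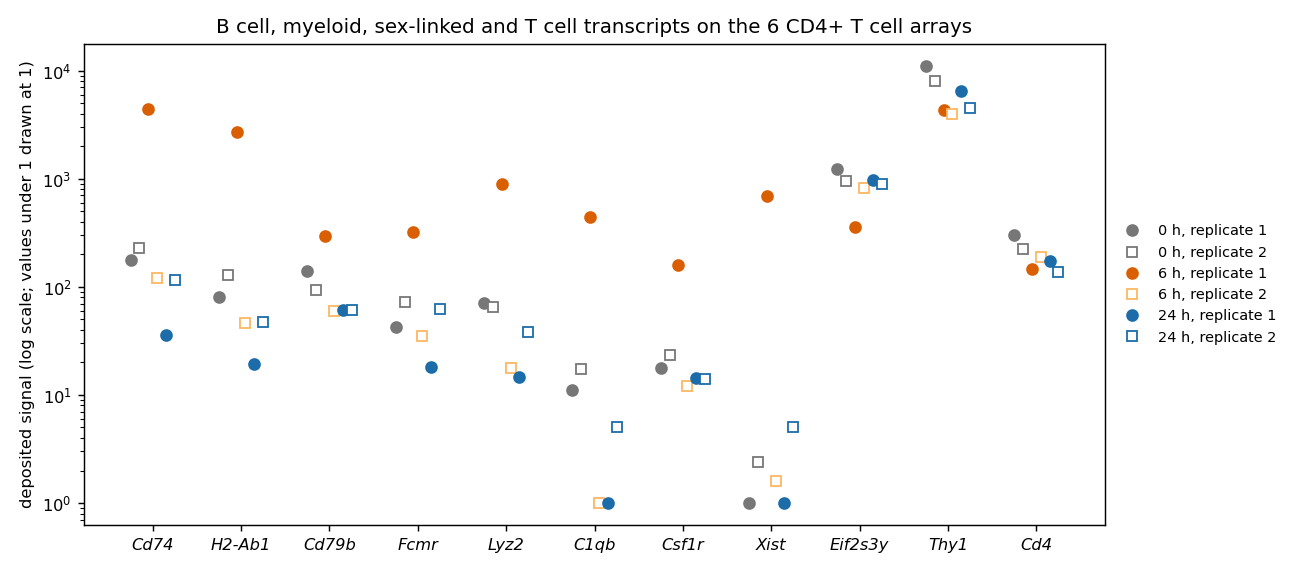
Deposited signal (linear intensity on a log axis, values under 1 drawn at 1) of marker genes of B cells, myeloid cells, sex and T cells on the 6 arrays of the IL-7 time course, 1 point per array. On 6 h replicate 1, Cd74 reaches 4418.3 and Lyz2 884.2, above every other array.

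The first comparison asks which transcripts differ from the 0 h level after 6 h of IL-7. Ecm1, which encodes a secreted matrix protein, rose most, 42.6-fold (log2 fold change 5.41 ± 0.18, SE, n = 2 arrays per time, adjusted p = 0.00066). Prnp, the gene of the cellular prion protein, rose 20.1-fold (4.33 ± 0.29), the actin motor gene Myo6 13.3-fold (3.74 ± 0.16) and the stress-responsive pseudokinase gene Trib3 13.4-fold (3.75 ± 0.33). Fosl2, a subunit of the AP-1 transcription factor, rose 11.8-fold (3.56 ± 0.14), and Crem, a transcription factor of the cyclic AMP response, 10.7-fold (3.42 ± 0.31). Adamtsl4 was not detected at 0 h and rose at least 14-fold. Among the genes that fell most, the heat shock gene Hsph1 fell by 3.16 ± 0.45 on the log2 scale, the transporter gene Slc16a5 fell by 3.06 ± 0.54, and the receptor gene Cd160 fell by 2.95 ± 0.24. Ddit4, an inhibitor of mTORC1, fell by 2.59 ± 0.27 and Dapl1 fell by 2.38 ± 0.13, and Lbp was at least 4.02-fold lower and not detected at 6 h.

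Of 17 measured targets of STAT5, the transcription factor activated by the IL-7 receptor, 9 rose, 1 fell and 7 did not pass the test (9 and 2 adjusted over the list alone). Bcl2, which protects T cells from apoptosis, rose 6.58-fold (2.72 ± 0.29, adjusted p = 0.0094), the cytokine gene Lta rose by 2.24 ± 0.27, and the feedback inhibitors Cish and Socs2 rose by 1.65 ± 0.17 and at least 3.78-fold. The list rose as a whole (median log2 fold change 1.11, camera adjusted p = 1.3e-05), with an adjusted p of 0.64 with an estimated correlation. Of 12 measured genes of regulatory T cells, 7 rose and 1 fell (8 and 1 adjusted over the list alone), led by Ecm1, the inhibitory receptor Ctla4 (3.30 ± 0.34) and Gpr83 (3.11 ± 0.22). The median of this list was 1.41 (adjusted p = 1.3e-05, or 0.41 with an estimated correlation), while the lineage factor Foxp3 stood at -0.12 ± 0.13 (adjusted p = 0.57). Of 20 measured T cell activation genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone), among them Bhlhe40 (3.13 ± 0.54), Tnfrsf18 (2.88 ± 0.30) and Irf4 (2.84 ± 0.37). Their median was 0.44 (adjusted p = 0.0012, or 0.64 with an estimated correlation), and 0.05 (adjusted p = 0.35) without 6 h replicate 1. Beside these rises, the B cell and myeloid markers, high on that array, had medians of 1.48 and 1.17 at 6 h (adjusted p = 0.13 and 0.14), and of -0.67 and -0.52 (adjusted p = 0.31 and 0.032) without it.

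Interferon-stimulated genes, an antiviral programme, were lower at 6 h. Of 29 measured, 0 rose, 12 fell and 17 did not pass the test (0 and 25 adjusted over the list alone), with a median of -1.12 (adjusted p = 9.1e-10, or 0.64 with an estimated correlation). Isg15 fell by 2.56 ± 0.59, with a standard deviation of 1.43 between the arrays at 6 h, Oasl1 fell by 2.43 ± 0.40 and Oasl2 fell by 2.21 ± 0.44. Of 29 measured ribosome biogenesis genes, 0 rose and 3 fell (1 and 6 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.0016, or 0.64 with an estimated correlation). These 3 were Grwd1 (-0.83 ± 0.19), Bop1 (-0.77 ± 0.16) and Ppan (-0.63 ± 0.14). Of 16 measured T cell identity genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.021, or 0.66 with an estimated correlation). They include the T cell receptor signalling genes Lat (-1.08 ± 0.18) and Themis (-1.03 ± 0.14), and Thy1 (-0.81 ± 0.17), whose second probe went the other way. Of 24 measured immediate early and heat shock genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.054, or 0.85 with an estimated correlation), and of -1.21 (adjusted p = 1.2e-07) without 6 h replicate 1. The T cell identity list had a median of -0.34 (adjusted p = 0.0062) without 6 h replicate 1 and an adjusted p of 0.14 without 6 h replicate 2, and the array of 6 h replicate 1 carried the markers of other cells described above.

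Further called list members at 6 h were Il4ra (1.73 ± 0.22), Il2ra, Klf2 (1.20 ± 0.16), Klf3, Tnfrsf4 (2.06 ± 0.13), Rora, Icos, Cd200, Nr4a2, Bcl2l11, Cenpa, Lig1, Odc1, Idh1, Xbp1 and Pdia4, which rose by 0.61 to 2.06. Members that fell were Jak3 (-0.86 ± 0.15), Cxcr6, Nkg7, Tnfsf10, Klrd1, Klra3, Itgae, Itgb7, Hspa1b (at least 3.16-fold), Kif23, Atic, Nme1, Idh2, Suclg1, Lss, Mthfd2, Hdac10 and Sirt7, at -2.29 for Itgae to -0.53 for Sirt7. The IL-7 receptor gene Il7r stood at 0.21 ± 0.12 (adjusted p = 0.32), with 2 of its 5 probes in this direction. The Th9 programme as a list, in which 4 of 11 rose and 1 fell (4 and 3 adjusted over the list alone), had a median of -0.42 but a mean of 0.44, and was not called (adjusted p = 0.77). Foxo1 (-0.26 ± 0.18), Foxp1 (0.53 ± 0.20), Gata3 (-0.72 ± 0.18) and Ep300 (-0.27 ± 0.14) did not pass the test either. Il9, Il21 and Spi1 were not among the features tested in these cells. In all, limma called 1043 of 11065 features, of which 454 rose and 589 fell, and 3234 had an unadjusted p under 0.05. The arrays of the groups did not overlap for 57.8% of the features, against 33.3% by chance. A fit of the 4 arrays at 0 h and 6 h alone called 184. The 24 h arrays, outside this comparison but part of its estimate of spread, thus raised the number of genes that passed. The count was 3 without 0 h replicate 1, 4 without 0 h replicate 2, 2645 and 1676 without 6 h replicates 1 and 2, and 148 and 127 without 24 h replicates 1 and 2. Only Ecm1, Fosl2 and Myo6 were called whichever array was left out.

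The second comparison sets 24 h of IL-7 against 0 h. Ecm1 stood 46.9-fold higher (5.55 ± 0.18, SE, n = 2 arrays per time, adjusted p = 0.00057), Prnp 16-fold (SE 0.29 on the log2 scale), Trib3 11.2-fold (3.48 ± 0.33) and Myo6 10.6-fold (3.40 ± 0.16). Adamtsl4, not detected at 0 h, rose at least 20.8-fold, and the receptor gene Gpr34 rose 9.12-fold (3.19 ± 0.23). The activation marker Cd69 fell 14.1-fold (-3.82 ± 0.44, adjusted p = 0.012), Cmpk2 9.75-fold (-3.29 ± 0.61) and Slc16a5 8.54-fold (-3.09 ± 0.54). The pancreatic amylase gene Amy2a5 fell by 3.37 ± 0.70, with a standard deviation of 1.72 between the arrays at 0 h.

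STAT5 targets were again higher: of 17 measured, 10 rose, 0 fell and 7 did not pass the test (13 and 1 adjusted over the list alone), with a median of 0.96 (adjusted p = 1.3e-07, or 0.41 with an estimated correlation). Bcl2 rose 9.39-fold (3.23 ± 0.29, adjusted p = 0.0069), Socs2 at least 8.27-fold, the survival kinase gene Pim1 5.15-fold (2.37 ± 0.14) and Cish 2.77-fold (1.47 ± 0.17). Of 12 measured regulatory T cell genes 7 rose and 0 fell (7 and 3 adjusted over the list alone), with a median of 1.16 (adjusted p = 0.0016, or 0.33 with an estimated correlation). Beside Ecm1 they included Capg (2.14 ± 0.20), Tnfrsf18 (2.13 ± 0.30) and Ctla4 (1.90 ± 0.34), and Foxp3 stood at -0.03 ± 0.13 (adjusted p = 0.9). All 17 measured genes of cholesterol synthesis were higher, 5 of them called (9 adjusted over the list alone), with a median of 0.49 (adjusted p = 9e-06, or 0.33 with an estimated correlation). Sqle and Cyp51, enzymes of the sterol pathway, rose by 1.14 ± 0.12 and 0.79 ± 0.17, and Stard4, a sterol carrier, by 0.94 ± 0.15.

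Of 29 measured interferon-stimulated genes, 0 rose and 17 fell (0 and 25 adjusted over the list alone), with a median of -1.42 (adjusted p = 4.1e-15, or 0.42 with an estimated correlation). Ifit3 fell 15.7-fold (-3.97 ± 0.63, adjusted p = 0.024), Oasl2 12.3-fold (-3.62 ± 0.44), Isg15 10.4-fold (-3.38 ± 0.59) and Oas2 10.2-fold (-3.35 ± 0.68). Of 24 measured immediate early and heat shock genes, 0 rose and 8 fell (0 and 16 adjusted over the list alone), with a median of -1.04 (adjusted p = 2.1e-09, or 0.5 with an estimated correlation). The inducible HSP70 genes Hspa1b and Hspa1a were at least 2.95-fold and 2.82-fold lower and not detected at 24 h, and Hsph1 fell by 2.21 ± 0.45. Of 16 measured T cell identity genes, 0 rose and 2 fell (0 and 7 adjusted over the list alone): Cd6 (-1.27 ± 0.26) and Cd4 itself (-0.61 ± 0.12). The median of this list was -0.42 (adjusted p = 0.00078, or 0.5 with an estimated correlation). Among 6 measured markers of natural killer cells, 3 fell (4 adjusted over the list alone), with a median of -1.14 (adjusted p = 0.0014, or 0.33 with an estimated correlation). They were Klrd1 (-1.33 ± 0.17), Klra7, at least 1.55-fold lower, and Klra3, at least 1.44-fold lower. Beside these falls, the 8 B cell and 14 myeloid markers had medians of -0.87 and -0.72 at 24 h (adjusted p = 0.63 and 0.21), with 7 and 12 of them lower, and of -1.08 and -0.74 (adjusted p = 0.059 and 0.005) without 6 h replicate 1.

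Further called list members at 24 h were Il2ra (1.83 ± 0.15), Il4ra (1.72 ± 0.22), Klf2 (0.81 ± 0.16), Klf3, Tnfrsf4, Bcl2l11, Cenpa, Amd2, Cad, Idh1, Eif4ebp1 and Kat2b, which rose by 0.69 to 1.83. Members that fell were Cd160 (-2.71 ± 0.24), Ddit4 (3.99-fold), Xcl1 (at least 3.13-fold), Bcl6 (-1.53 ± 0.29), Jak3, Irf1, Ly6c1, Itgb7 and Hdac10. Il7r stood at 0.43 ± 0.12 (adjusted p = 0.093), Foxo1 at -0.57 ± 0.18, Foxp1 at 0.18 ± 0.20, Gata3 at -0.57 ± 0.18 and Ep300 at -0.13 ± 0.14, none of which passed the test. Irf4 was not detected at 24 h and did not pass the test either (adjusted p = 0.73). In all, limma called 682 of 11065 features, of which 365 rose and 317 fell, and 2800 had an unadjusted p under 0.05. The groups did not overlap for 63.3% of the features, against 33.3% by chance. A fit of the 4 arrays at 0 h and 24 h alone called 2436. The 6 h arrays, outside this comparison but part of its estimate of spread, thus lowered the number of genes that passed. The count was 2 and 3 without 0 h replicates 1 and 2, 1 and 2 without 24 h replicates 1 and 2, and 2411 and 2418 without 6 h replicates 1 and 2. Only Ecm1 was called whichever array was left out.

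**Figure D2:**
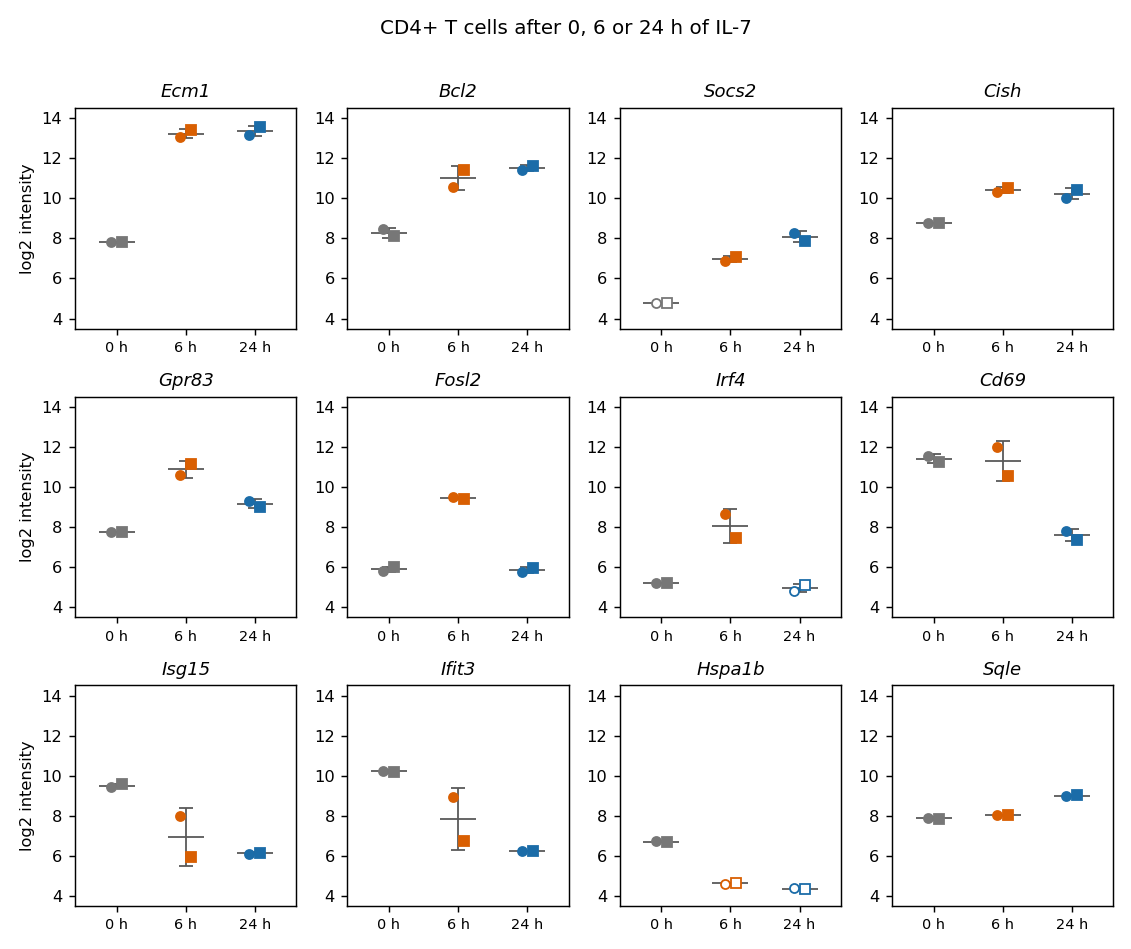
Normalised log2 intensity of 12 genes on the arrays at 0, 6 and 24 h of IL-7 (n = 2 per time). Circles are replicate 1 and squares replicate 2, open symbols mark a detection p of 0.01 or more, and bars show the mean ± SD. Ecm1 goes from a mean of 7.82 at 0 h to 13.23 at 6 h and 13.37 at 24 h, and Fosl2 from 5.89 to 9.45 and back to 5.84.

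Both times share the arrays at 0 h. Among the features called at both, 401 moved in the same direction (191 rose, 210 fell) and 2 in opposite directions, which is 38.4% of the calls at 6 h and 58.8% of those at 24 h. Ecm1, Prnp, Myo6, Bcl2 and Socs2 rose at both times, and Isg15, Oasl2, Cd160 and Hspa1b fell at both. Independent lists of the same sizes would share 31.9 features in the same direction (15 rising, 16.9 falling). Unchanged groups simulated against the same controls shared at most 2 in 100 draws, 0.09 on average. The simulation leaves out real effects, so few calls can arise in it and its small overlap does not measure what shared controls add. The independent lists leave out the shared controls, which are too few to split, so part of the excess may come from these controls. The overlap was 2 without 0 h replicate 1, 3 without 0 h replicate 2, 1550 and 761 without 6 h replicates 1 and 2, and 1 and 2 without 24 h replicates 1 and 2.

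The third comparison sets 24 h against 6 h within the time course, and asks what changed between these times. Fosl2 fell by 3.61 ± 0.14 (12.2-fold, SE, n = 2 arrays per time, adjusted p = 0.0014), to a mean of 5.84 against 5.89 at 0 h. Cd69 fell 13-fold (-3.70 ± 0.44), Irf4, a transcription factor of activated lymphocytes, was at least 7.47-fold lower, and the stress gene Gadd45b at least 6.08-fold lower. Crem fell 5.5-fold (-2.46 ± 0.31), P2ry14 5.67-fold and Gch1, the first enzyme of tetrahydrobiopterin synthesis, 3.5-fold (-1.81 ± 0.13), while Ramp3 was at least 3.87-fold lower. Myl10 rose at least 5.74-fold, Drc1 4.93-fold (2.30 ± 0.15), the cytotoxic granule gene Nkg7 2.85-fold (1.51 ± 0.18) and Grm6 at least 2.09-fold. Stx1a (1.26 ± 0.14), Setbp1 (1.07 ± 0.13) and Tnik (1.07 ± 0.13) rose as well. Of the features called at 6 h, 28 moved back between 6 h and 24 h, 24 that had risen and 4 that had fallen. Both calls rest on the same 6 h arrays, with opposite sign, so a deviation of these arrays can produce part of this count.

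Of 20 measured T cell activation genes, 0 rose and 3 fell from 6 h to 24 h (1 and 10 adjusted over the list alone), Cd69, Irf4 and Tnfrsf4 (-1.15 ± 0.13). Their median was -1.19 (adjusted p = 2.6e-06, or 0.46 with an estimated correlation), and -0.64 (adjusted p = 3.1e-06) without 6 h replicate 1. Of 24 immediate early and heat shock genes only Fosl2 fell (1 adjusted over the list alone), with a list median of -0.64 (adjusted p = 2.6e-06, or 0.52 with an estimated correlation), and of -0.29 (adjusted p = 0.018) without 6 h replicate 1. Of 17 cholesterol synthesis genes 2 rose (8 adjusted over the list alone), Sqle (0.98 ± 0.12) and Idi1 (0.91 ± 0.12), with a list median of 0.43 (adjusted p = 2.6e-06, or 0.35 with an estimated correlation). The 29 ribosome biogenesis genes had a median of 0.32 with 0 called (5 adjusted over the list alone; adjusted p = 2.6e-06, or 0.46 with an estimated correlation). The 19 polyamine and nucleotide synthesis genes had a median of 0.36 with 0 called (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0027, or 0.46 with an estimated correlation, and 0.078 without 6 h replicate 2). Of 12 regulatory T cell genes 2 fell, Gpr83 (-1.71 ± 0.22) and Tnfrsf4 (3 rose and 5 fell adjusted over the list alone; median -0.60, adjusted p = 0.029, or 0.46 with an estimated correlation), and the median was -0.32 (adjusted p = 0.021) without 6 h replicate 1. The 6 markers of natural killer cells had a median of -0.48 with 0 called (0 adjusted over the list alone; adjusted p = 0.0054, or 0.46 with an estimated correlation).

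The remaining lists called between 6 h and 24 h lost their call without 6 h replicate 1, the array with markers of other cells. B cell markers had a median of -2.39 (adjusted p = 0.0027) with all arrays and of -0.30 (0.6) without it, and myeloid markers -1.67 (0.00011) and -0.08 (0.72). Interferon-stimulated genes went from -0.32 (0.00097) to -0.01 (0.76), Tfh genes from -0.94 (0.005) to -0.20 (0.26), G2/M genes from -0.48 (0.0037) to -0.20 (0.24) and DNA replication genes from -0.21 (0.0027) to -0.13 (0.19). The genes of the Th9 programme, of which Irf4, Relb (-1.53 ± 0.19) and Tnfrsf4 fell, had a median of -0.31 (0.0027) with it and 0.03 (0.18, the test pointing down) without it. STAT5 targets had a median of 0.40 (0.045) with it and 0.27 (0.6) without it, and an adjusted p of 0.13 without 6 h replicate 2 and 0.28 without 24 h replicate 2. Features called in these 8 lists were 3 of the Th9 programme and 1 STAT5 target, Tnfrsf4, and 0 in the others. Adjusted over the list alone, 3 fell in the Th9 programme, 5 rose and 2 fell among STAT5 targets, 1 rose and 3 fell among G2/M genes, 3 fell among DNA replication genes, 2 among Tfh genes and 1 among interferon-stimulated genes, and 0 changed among B cell and myeloid markers. With an estimated correlation these 8 lists had adjusted p-values of 0.46 to 0.52. Socs2 (1.13 ± 0.17, adjusted p = 0.07), Bcl2 (0.51 ± 0.29), Cish (-0.18 ± 0.17), Klf2 (-0.39 ± 0.16), Il7r (0.22 ± 0.12), Foxo1 (-0.31 ± 0.18), Foxp1 (-0.35 ± 0.20), Foxp3 (0.09 ± 0.13), Gata3 (0.15 ± 0.18) and Ep300 (0.14 ± 0.14) did not pass the test. In all, limma called 44 of 11065 features, of which 12 rose and 32 fell, and 1884 had an unadjusted p under 0.05. The groups did not overlap for 47.3% of the features, against 33.3% by chance. The count was 319 and 1476 without 6 h replicates 1 and 2, 1 without either 0 h array, and 0 and 1 without 24 h replicates 1 and 2, the 0 with 862 at an unadjusted p under 0.05. Fosl2 was called in 5 of these 6 fits.

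The fourth comparison asks what prior IL-7 leaves in Th9 cells. Whether the cells without IL-7 were also kept for 48 h before the Th9 culture is not given in the sources used here, so each difference covers IL-7 and any difference in that time. Il9 itself stood at a mean log2 intensity of 9.42 ± 0.79 after IL-7 and 8.79 ± 0.54 without (SD, n = 3 arrays per group), a difference of 0.63 ± 0.39 (SE) that did not pass the test (adjusted p = 0.67). Il17f, a cytokine of Th17 cells, rose 8.71-fold (3.12 ± 0.33, adjusted p = 0.006), from 5.69 ± 0.59 to 8.81 ± 0.50. Il21, a cytokine that acts on B cells and T cells, was not detected without IL-7 and rose at least 3.95-fold. Il1rn, the antagonist of the interleukin-1 receptor, rose 6.53-fold (2.71 ± 0.22, adjusted p = 0.0017), and Pdpn, which encodes podoplanin, 3.36-fold (1.75 ± 0.26). Il3, a growth factor of blood cell precursors, fell by 2.09 ± 0.20 (adjusted p = 0.0027), Phlda1 fell by 2.54 ± 0.35 and the transcription factor Tox fell by 1.42 ± 0.22. The vasopressin receptor gene Avpr1a was at least 7.58-fold lower. The globin genes Hbb-bs and Hbb-bt, known from red blood cells, were lower as well, Hbb-bs by a log2 fold change of -3.12 ± 0.25 and Hbb-bt at least 5.57-fold.

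Smaller rises were those of Maml2 (1.29 ± 0.14), Cog6 (1.04 ± 0.17), Chil3 (at least 1.62-fold) and Srxn1 (at least 1.6-fold), and smaller falls those of Zcchc18 (-1.73 ± 0.28), Bmyc (-1.27 ± 0.15) and the enolase gene Eno3 (-1.22 ± 0.18). The IL-7 targets that were higher in naive cells stood near 0 in Th9 cells, with Bcl2 at -0.17 ± 0.23, Cish at -0.03 ± 0.15 and Socs2 at -0.14 ± 0.15. Of 18 measured STAT5 targets 0 changed (1 rose adjusted over the list alone), with a median of -0.06 and a mean of 0.05 (adjusted p = 0.83). Il7r (0.15 ± 0.32), Irf4 (0.36 ± 0.15), Gata3 (-0.59 ± 0.17), Foxo1 (0.41 ± 0.19), Foxp1 (0.12 ± 0.16), Foxp3 (-0.16 ± 0.14), Klf2 (-0.19 ± 0.26) and Ep300 (-0.20 ± 0.17) did not pass the test, with adjusted p-values of 0.27 or more. Spi1 was not among the features tested. In all, limma called 33 of 9635 features, of which 15 rose and 18 fell, and 956 had an unadjusted p under 0.05. The groups did not overlap for 14.7% of the features, against 10% by chance. The count was 10, 8 and 11 without replicates 1, 2 and 3 of the cells without IL-7, and 13, 14 and 62 without replicates 1, 2 and 3 of the cells after IL-7. Il17f, Il1rn, Il3, Hbb-bs and Hbb-bt were called in all 6 of these fits, as were AA467197 and a probe with no symbol that rose by 3.56, both named after their values were seen. The array of replicate 1 after IL-7 differed from the other 5 in Xist, a sex-linked transcript picked as above, with a signal of 792 there and no detection on the others, while Eif2s3y was detected on the other 5 only.

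**Figure D3:**
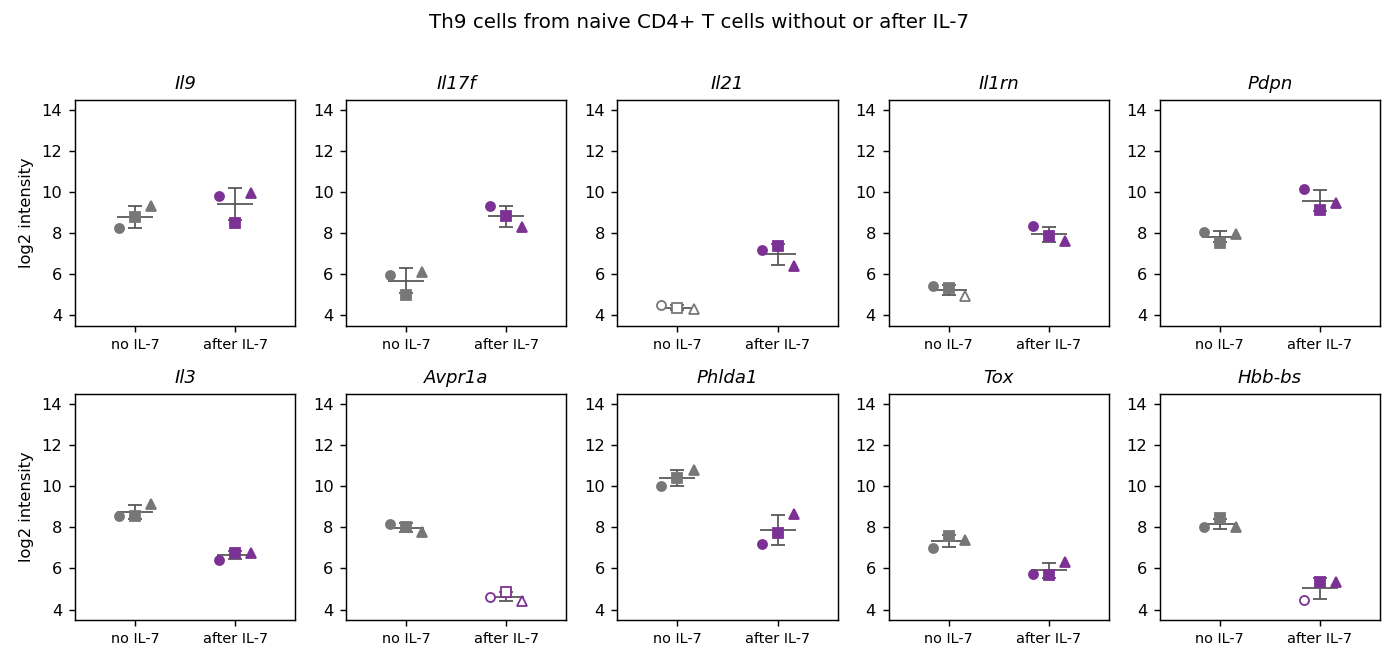
Normalised log2 intensity of 10 genes in Th9 cells grown without IL-7 and after 48 h of IL-7 (n = 3 arrays per group). Circles, squares and triangles are replicates 1, 2 and 3, open symbols mark a detection p of 0.01 or more, and bars show the mean ± SD. Il17f goes from 5.69 to 8.81 on average, while Il9 overlaps between the groups (8.79 and 9.42).

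Th17 genes rose as a list after IL-7: of 7 measured, 1 (Il17f) rose, 0 fell and 6 did not pass the test (5 and 1 adjusted over the list alone), with a median of 0.81 (adjusted p = 0.00053, or 0.18 with an estimated correlation). Of 7 Tfh genes, Il21 rose and Tox fell (4 and 1 adjusted over the list alone), with a median of 0.52 (adjusted p = 0.0048, or 0.19 with an estimated correlation). Without replicates 1, 2 and 3 after IL-7 in turn, the Tfh list had adjusted p-values of 0.26, 0.18 and 0.092. Of 18 genes of the Th9 programme, Il21 rose and Il3 fell (6 and 2 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.042, or 0.25 with an estimated correlation). This list had adjusted p-values of 0.14, 0.12 and 0.19 without replicates 1, 2 and 3 after IL-7, and 0.067 without replicate 2 of the cells without IL-7. The 11 measured receptors and signalling genes of the gamma-chain cytokines, the family of IL-7, had a median of 0.26 with 0 called (1 adjusted over the list alone; adjusted p = 0.0031, or 0.23 with an estimated correlation, and 0.11 without replicate 2 after IL-7).

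The remaining called lists had 0 called members. The 16 cholesterol synthesis genes had a median of -0.20 (0 adjusted over the list alone; adjusted p = 0.0031, or 0.18 with an estimated correlation) and 10 B cell markers one of -0.37 (0 adjusted over the list alone; adjusted p = 0.0031, or 0.18 with an estimated correlation). The 14 interferon-stimulated genes had a median of 0.20 (1 adjusted over the list alone; adjusted p = 0.033, or 0.26 with an estimated correlation). Its adjusted p was 0.084 without replicate 2 of the cells without IL-7 and 0.14 without replicate 2 after IL-7. The 19 amino acid response genes had a median of -0.26 (0 adjusted over the list alone; adjusted p = 0.033, or 0.4 with an estimated correlation). Their adjusted p was 0.16 without replicate 2 of the cells without IL-7, and 0.084 and 0.15 without replicates 2 and 3 after IL-7. The 5 Th1 genes had a median of 0.68 (0 adjusted over the list alone; adjusted p = 0.044, or 0.26 with an estimated correlation). Here the adjusted p was 0.067 and 0.11 without replicates 2 and 3 of the cells without IL-7, and 0.11 and 0.09 without replicates 1 and 2 after IL-7.

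**Figure D4:**
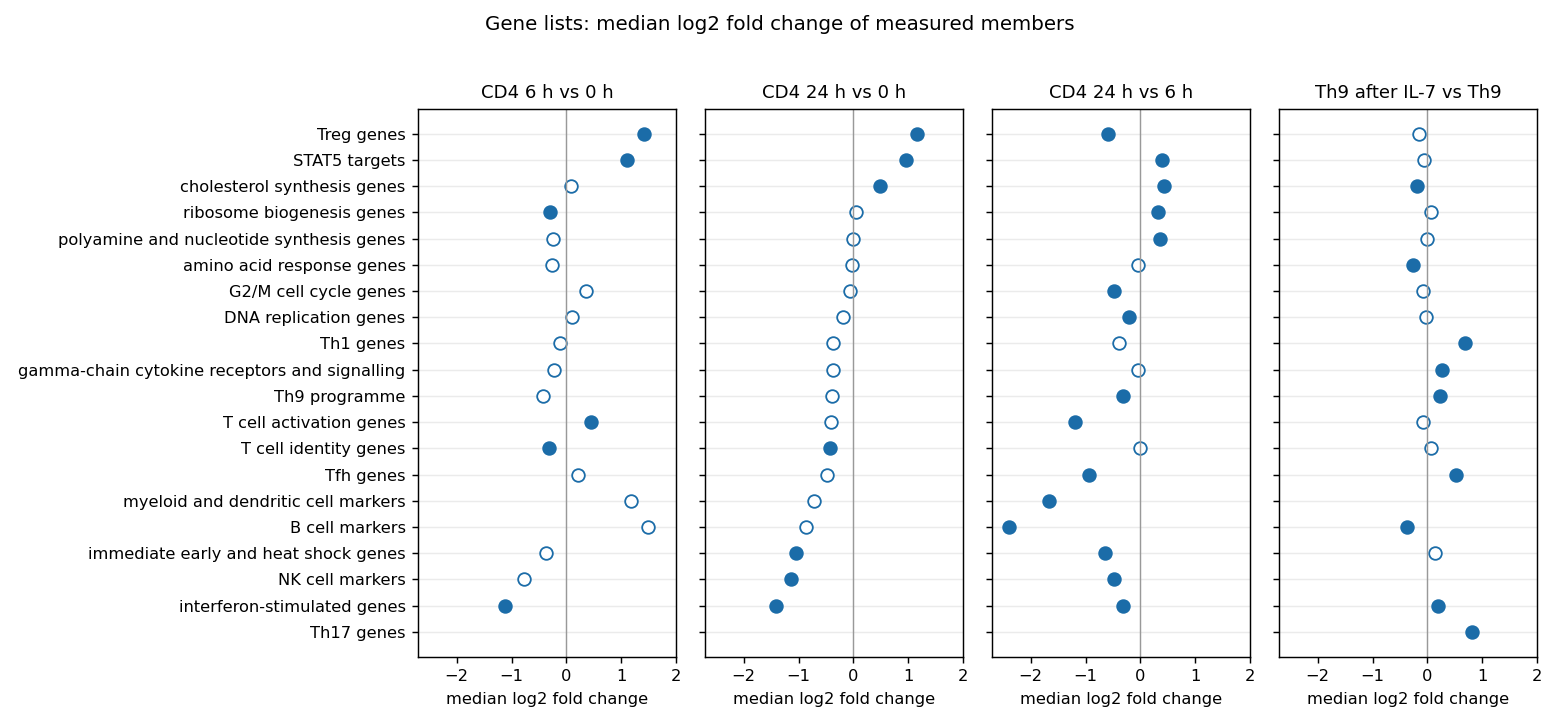
Median log2 fold change of 20 gene lists in the 4 comparisons, 1 point per list and comparison. Filled points are lists called by camera with the preset correlation, 6, 7, 15 and 9 lists in the order of the comparisons. Interferon-stimulated genes lie at -1.12 and -1.42 at 6 h and 24 h of IL-7 and at 0.20 in Th9 cells.

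The last comparison asks whether IL-7 shifts the same genes in naive cells at 24 h and in Th9 cells grown after IL-7. Bcl2 responded by 3.43 in naive cells and -0.16 in Th9 cells, a difference of 3.59 ± 0.41 (SE, n = 2 and 3 arrays per group, adjusted p = 0.002). Cish differed by 1.57 ± 0.23, Pim1 by 2.62 ± 0.36, Sqle by 1.33 ± 0.19 and Cd69 by -4.04 ± 0.54. Socs2, the interferon-stimulated genes Ifit3 and Oasl2, and Il1rn were called too, but Socs2 was not detected at 0 h, Ifit3 and Oasl2 were not detected in Th9 cells and Il1rn was not detected in naive cells, so the sizes of these differences are not given. In all, limma called 459 of 12248 features in this contrast, of which 252 had the higher response in naive cells and 207 the lower, and 2210 had an unadjusted p under 0.05. Only AA467197 (1.94 and 1.63) and Phlda1 (-1.38 and -2.54) were called in both experiments, named here after their values were seen. Across 8831 genes and probes tested in both, the fold changes correlated at 0.014 (Pearson) and -0.025 (Spearman), and at 0.028 over the 457 called in naive cells. Genes are not independent replicates, and the spread of the fold changes was 0.47 in naive cells and 0.26 in Th9 cells (SD across genes). The experiments differ in the length of IL-7 exposure, in the later culture and in the chip. The count was 66 and 72 without 0 h replicates 1 and 2, 76 and 64 without 24 h replicates 1 and 2, and 286 and 245 without replicates 1 and 2 of the Th9 cells without IL-7.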

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

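The tests of 6 h replicate 1, and that of Hbb-bs alone below, were chosen only after the results were seen, while the other tests of the globin genes and those of the Th9 splits were fixed beforehand. The IL-7 response differed between naive cells at 24 h and Th9 cells for 459 of 12248 features by a test of the difference itself (limma), as for Bcl2 (3.59 ± 0.41) and Cd69 (-4.04 ± 0.54). Within the time course, the responses at 24 h and 6 h differed for 44 of 11065 features by the same kind of test, as for Fosl2 (-3.61 ± 0.14), and this count was 319 and 1476 without 6 h replicates 1 and 2, and 0 or 1 without any other array.

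The array of 6 h replicate 1 stood apart from its partner. Markers of B cells exceeded the highest of the other 5 arrays by a median of 3.27 on the log2 scale (8 genes) and those of myeloid cells by 2.57 (14 genes), in line with cells other than T cells in this sample. By deposited signal, the median ratio of these markers to the highest signal on the other arrays was 6.21. Ctss (0.65), S100a9 (0.66), S100a8 (0.904) and Siglech (0.908) lay below 1. A lower overall signal on the array therefore cannot produce the excess of these markers as a set. Whether it adds to the other differences of this array, which had the lowest mean signal of the time course (157.6), was not tested. An exchange of time labels with a 24 h array is excluded by the correlation of 0.992 between the 24 h arrays, against 0.982 and 0.984 for 6 h replicate 2 with either of them. Xist at 692 together with Eif2s3y at 358 is what RNA from animals of both sexes in this sample would give. How these transcripts came into the sample was not tested.

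Globin transcripts were lower in Th9 cells after IL-7, with Hbb-bs at -3.12 ± 0.25 over all arrays. Sex of the animals is excluded as the source, since Hbb-bs alone, detected on the 5 arrays left without the 1 array with Xist signal, differed there by a log2 value of -2.82. The planned mean of Hbb-bs and Hbb-bt was -2.77 without that array, with Hbb-bt not detected after IL-7. Fewer red cell precursors carried through the culture were tested on the other erythroid genes, of which only Tfrc (1 gene, -0.07) was measurable. Tfrc is also expressed by dividing T cells, so carry-over and a response of the Th9 cells to IL-7 are both left open.

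The split of the 6 Th9 arrays by IL-7 was set against the other ways of dividing them into 3 and 3. It was the only 1 of 10 splits with as many as 33 genes called by limma, the highest of the others being 0 (with 222 to 931 genes at an unadjusted p under 0.05, against 956). It was also the only 1 of 10 with as many as 9 lists, the highest other being 7. With 10 splits the share cannot go under 0.05, so an origin of these calls in arrays that happen to lie together stays open. Each other split sets 2 arrays of one group and 1 of the other against the rest, so it keeps part of any IL-7 effect.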

How the results depend on the processing

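Scaling by the factors of the second table was chosen only after the data were seen, and the other alternatives were fixed before. The planned fit on the second table itself was not run, since its probe names could not be used. For 6 h against 0 h, 9 alternatives gave 728 to 1461 genes, no detection filter 519, the replicate block 681, only the 4 arrays compared 184, and leaving out 1 array 3 to 2645. For 24 h against 0 h, 7 gave 482 to 932, no filter 211, array weights 2170, the block 449, all 12 arrays in 1 fit 1025, only 4 arrays 2436, and leaving out 1 array 1 to 2418. For 24 h against 6 h, 3 gave 46 to 50, no background correction 5, median centring 252, scaling by the factors 6, no filter 7, a variance trend 73, weights 13, the block 5, all 12 arrays 170, only 4 arrays 4, and leaving out 1 array 0 to 1476 (limma, 862 at an unadjusted p under 0.05 for the 0). For Th9 cells, 4 gave 23 to 46, the block among them with 23, no background correction 17, median centring 84, normalising over all 12 arrays 15, the factors 21, no filter 4, a variance trend 103, all 12 arrays in 1 fit 101, and leaving out 1 array 8 to 62. For the difference of effects, 4 gave 309 to 587, array weights 1002, and leaving out 1 array 64 to 676. A lone array left in a group was assumed to vary like the others. Leaving out 1 array also lowers the residual degrees of freedom. Without an array at 0 h or 24 h, the 6 h pair carries more of the estimate of spread. Calls lost in such fits therefore need not mean that the changes are smaller. No filter adds dim features to the correction. For 24 h against 0 h, the 6 h arrays entered only through normalisation, the choice of features and the shared estimate of spread. With the 4 compared arrays alone 2436 genes were called in place of 682, so the 6 h arrays, which correlated at 0.962, lowered this count. For 6 h against 0 h the 24 h arrays, which correlated at 0.992, entered in the same way. They raised that count from 184 to 1043. The cause of the other shifts was not tested.

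With median centring the median log2 fold change of all features was -0.247 at 6 h, -0.116 at 24 h, 0.142 for 24 h against 6 h and -0.15 in Th9 cells, where the fits of the report had -0.034, -0.003, 0.039 and -0.012. Its calls, tested against 0 and not against these medians, were 305 rising and 1018 falling at 6 h and 312 rising and 552 falling at 24 h. At 24 h the majority thus turned from the 365 rising and 317 falling of the report, while the factors gave 292 and 190. Lists called at 6 h numbered 14 with no filter and 6 to 11 with 1 array left out. They numbered 8 to 17 for 24 h against 6 h and 3 to 10 in Th9 cells with 1 array left out. With an estimated correlation 0 lists were called in each comparison (camera of limma, with 1, 3, 1 and 5 lists at an unadjusted p under 0.05 in the order of the report). That form of camera also rests on 3 or 4 residual degrees of freedom. At 24 h against 0 h the cholesterol list had an estimated correlation of 0.001, below the preset 0.01. Its adjusted p still went from 9e-06 to 0.33. The loss of these calls thus does not measure correlation between genes alone. The overlap of 6 h and 24 h was 130 with no filter, 275 with the block and 1 to 1550 with 1 array left out. The correlation between naive and Th9 responses ran from -0.021 to 0.05 with 1 array left out and from 0.006 to 0.014 otherwise.

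Same-numbered arrays had correlated deviations of 0.06, 0.14 and -0.19 in the time course and -0.06, -0.10 and 0.29 in Th9 cells. With 2 arrays per time, differently numbered arrays must have the same values with the opposite sign, so the time course cannot decide whether numbers pair the samples. Not every Th9 array correlated best with its own number. Xist and Eif2s3y show that the arrays of replicate 1 there do not come from the same animal. Whether they are paired in another way, and whether the other numbers are paired, stays unknown. Of 155 calls of named genes, 110 held with no background correction, 141 with median centring, 116 with the factors, 152 with a variance trend and 115 with the block, and none turned under these. With 1 array left out, 382 of 908 held, 525 were weaker and 1 turned.

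Values that changed sign belonged to genes near 0 that did not pass the test, apart from Klra3. Median centring put Il7r at -0.11 at 6 h, and Foxp1 at -0.04 and Il7r at -0.03 in Th9 cells. With 1 array left out, Foxp1 at 24 h ran from -0.05 to 0.42, Foxp3 at 24 h from -0.11 to 0.04, and for 24 h against 6 h Cish ran from -0.38 to 0.02 and Gata3 from -0.08 to 0.37. In Th9 cells Cish ran from -0.09 to 0.05, Il7r from -0.29 to 0.40, Klf2 from -0.38 to 0.13 and Bcl2 from -0.35 to 0.09. Klra3 was not detected at 24 h, so its fitted values there, from -1.13 to 0.00, do not measure the size of the fall, and the last arose without 0 h replicate 2, where another of its 2 probes stood for the gene. The cause of the other sign changes was not tested. The number of arrays limits all of these values.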

Other observations

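Histone genes and the cytokines below were chosen only after their values were seen. Most genes of the core histones, which cells make largely while they copy their DNA, were lower after IL-7. Of 41 measured in naive cells, 0 rose and 17 fell at 24 h against 0 h, and 39 were lower, with a median log2 fold change of -1.39 (n = 2 arrays per time). H4c6 stood at -2.46 ± 0.23 (SE, limma adjusted p = 0.0076). At 6 h 0 rose and 17 fell, with a median of -0.99, and from 6 h to 24 h 0 were called, with a median of -0.46. In Th9 cells after IL-7, 35 of 42 were lower with 1 called and a median of -0.30. Since the set was chosen from these values, no test of it as a list is given. The list of DNA replication genes, fixed beforehand, was not called in naive cells against 0 h. Of its 22 measured members 0 were called at 24 h (median -0.19, camera adjusted p = 0.32), and at 6 h 1 rose and 0 fell (median 0.11, adjusted p = 0.3). Near-identical histone genes can share signal between their probes, so these are fewer independent measurements than genes.

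Other cytokine genes of helper T cells did not pass the test in Th9 cells after IL-7 (n = 3 arrays per group). Il10 stood at 1.66 ± 0.34 (SE, limma adjusted p = 0.1), Il24 at 1.26 ± 0.28 (0.13), Il2 at 1.01 ± 0.23 (0.14) and Il13 at 0.76 ± 0.15 (0.1). Il4 stood at -0.75 ± 0.22 (0.27), Il5 at -0.82 ± 0.35 (0.48), Ifng at 0.68 ± 0.29 (0.48) and Csf2 at -0.05 ± 0.40 (0.98). The AP-1 factor gene Batf stood at 0.67 ± 0.13 (0.094) and the chemokine receptor gene Ccr6 at -0.88 ± 0.21 (0.15).

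Replicate 1 of the Th9 cells after IL-7 had Xist at 792 and no detected Eif2s3y, while replicate 1 without IL-7 had Eif2s3y at 648 and no detected Xist.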
